A study of Mus musculus with 4 samples.

How the data were processed

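Total RNA from aortic arches of Ldlr-/- mice with a human CETP transgene was analysed in 4 pools of 10 mice, taken after 4, 8, 12 and 16 weeks on a Western diet. Per the labels, RNA was purified on silica spin columns with DNase treatment, amplified with an aminoallyl kit and labelled, with the reference in Cy3 and the time-point pool in Cy5 on each of 4 arrays. The dyes were not swapped. The reference was an equal mix of the RNA of the 4 pools. Samples were grouped by the time point in the labels, with 1 pool per group.

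The values used here are the authors' processed table, 1 value per probe and array, and the deposited values are read here as log10 ratios. Scanner software, background correction, normalization and the reason for empty cells are not given in the sources used here. The deposited table states neither the log base nor the direction of the ratio, and both were inferred from the design. If the reference is an equal mix, the mean of the 4 linear ratios of a probe is 1, so its log2, called closure here, is 0. Under base 10 with pool over reference the median closure of the 1498 probes that varied most was 0.0107 log2 and the slope of closure on variance 0.169. Under base 2 the slope was -0.637, under natural logarithms -0.707, and with the ratio turned round under base 10 it was 6.47. The slope of the mean log10 ratio on its variance was -0.981, where pool over reference in base 10 predicts -1.15 and base 2 predicts -0.347. Closure would also hold by construction if the reference values had been computed from the 4 arrays. Over 39103 probes closure had an SD of 0.0375 log2, and 99.9% lay within 0.3 of 0. This SD does not favour base 10, since base 2 gives 0.0175 and most probes hardly vary, so the inference rests on the variable probes and the slopes. Medians of the deposited log10 ratios were 0.0058, 0.0028, 0.00835 and 0.0007 at 4, 8, 12 and 16 weeks, so each array lies near 0. The scale and direction rest on closure, and how the arrays came to be centred stays unknown. A dye effect of a probe is shared by the arrays and cancels in differences between them, but not in ratios to the reference.

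The 4 arrays had 150, 66, 157 and 122 empty cells, and probes without all 4 values were left out. Probes were named from the platform's annotation, with 23282 of 39555 probes carrying 1 symbol, 0 carrying several and 16273 unnamed here. Of the named probes 16573 had a current symbol, 6594 were updated through a synonym in the RefSeq gene table of assembly GRCm38.p6, and 115 kept their name unmatched. That assembly was used for names alone, and no coordinates are given. Named probes with all 4 values numbered 22944 and gave 19626 genes, each the mean of its probes, of which 16812 had 1 probe and 2814 had several. Among the genes at least 2-fold apart between 16 and 4 weeks, 91 had several probes and in 4 of them the probes differed in sign.

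Ratios were converted to log2. Differences between pools were counted at 2-fold, that is 1 log2 unit, with no test, since no time point has a second pool. A linear trend on week was fitted with limma's lmFit and eBayes over the 4 arrays, with 2 residual degrees of freedom and Benjamini-Hochberg adjustment over 19626 genes at 0.05. Its residual holds departure from a straight line as well as error between pools and arrays. Tested on simulated data with 200 changed genes, the trend test recovered 0% of genes with a 16 minus 4 week change of 1 log2. At changes of 2 and 3 log2 it recovered 91% and 99.5%, with 7.14% and 7.01% wrong calls. The simulated changes were exactly linear, with errors independent between genes. These shares therefore do not hold for changes that bend over time or for errors that genes share. Ibsp, with a real difference of 4.98 log2, had an adjusted p of 0.451 by limma. Before the data were examined, 32 gene lists were fixed, as were the designs, the alternatives and the rule for named genes. The lists cover macrophages and foam cells, lysosomes and cathepsins, MHC class II, T cells, B and plasma cells, thymocytes and lymph node tissue, mast cells and granulocytes, interferon-stimulated genes, chemokines and adhesion molecules, complement, contractile smooth muscle, fibrillar matrix and elastic fibre, metalloproteinases and inhibitors, cartilage and bone, endothelium, white and brown adipocytes, mitochondrial respiration, cardiac and skeletal muscle, nerve and Schwann cells, thyroid, parathyroid and airway epithelium, erythroid cells, sterol synthesis, LXR targets, fatty acid synthesis, fasting and PPAR response, cell cycle, circadian clock, immediate early and heat shock genes, TGF-beta and injury response, and ribosomal proteins. Of their 609 genes 551 were measured, and 6 genes sit in several lists. Lists of 28 pancreatic acinar genes, further acinar genes, islet, hepatocyte and Y-linked genes were written after the values were seen. A list's median difference was placed as a percentile among 10000 random lists of the same size, and called apart under 2.5 or over 97.5. The table holds no expression levels, so random lists could not be matched on them. As a substitute chosen after the data were seen, members were matched in 20 bins of each gene's range over the 4 arrays. That range contains the differences being ranked. A matched percentile therefore weighs mainly whether members share a direction, and it is not an independent null. Tested on simulated lists of 20 genes, the unmatched percentile called 4.6% of lists with no shift and 98.2% with a shift of 0.25 log2. Camera in limma was run on the trend with a preset correlation of 0.01 and with an estimated correlation. The estimate ran from -0.07 for the thyroid, parathyroid and airway list to 0.95 for the MHC class II list. With an estimated correlation camera rests on the 2 residual degrees of freedom of the fit, so hardly any list could pass. A high adjusted p from it is therefore no evidence against a list. The preset treats members as nearly independent, so its small p-values do not measure differences between pools. The share of 4.6% does not carry over to lists whose members move together, and their rate of false calls is unknown.

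Named genes were, for 16 against 4 weeks, the 12 largest differences each way among genes that moved the same way at each step, for each pool the 6 highest and 6 lowest against the mean of the others, for each step the 4 largest each way, and for each list up to 4 members by the size of the 16 minus 4 week difference or at another time point. Clone and other names without a described gene were skipped. Genes with a called trend are listed in full in addition. Alternatives changed the scaling (array medians set to 0, quantile normalization), the gene value (median of probes, or only genes whose probes lie within 1 log2), the probe filter (closure within 0.3), the thresholds (1.5-fold and 3-fold, adjusted p of 0.1), the contrast, the time scale, the variance model and the pools used. Tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.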

Results

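Gene expression was measured in the aortic arch, the curved first part of the aorta where mice develop atherosclerotic lesions early, at 4 times on a diet that raises blood cholesterol. The mice lacked the LDL receptor and carried a transgene for human CETP, a plasma protein that moves cholesteryl esters between lipoproteins and that mice do not have. Feeding of a Western diet with 9% fat and 0.15% cholesterol began when the animals were 8 weeks old. Arches were taken after 4, 8, 12 or 16 weeks of feeding, and the arches of 10 mice were pooled at each time, giving 4 pools. Each pool, labelled with Cy5, was hybridised on 1 array against the same Cy3-labelled reference, an equal mix of the 4 pools that stood for 40 mice. There was no group without the diet, and the animals grew older as feeding went on, so time on diet and age were not separated.

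The arrays held 39555 probes, of which 39103 had a value on all 4 arrays, and the named probes gave 19626 genes. Values are log2 ratios of pool over reference, so the difference between 2 pools is their log2 ratio to each other. With 1 pool and 1 array per time point no difference between pools has a replicate check, and the number of arrays limits the precision. Rises and falls are named as such only for genes that passed the test of a linear trend. As a partial measure of technical spread, the 16 minus 4 week difference varied between probes of the same gene with a pooled SD of 0.30 log2 over 2814 genes. The median SD was 0.13. Errors of an array, its labelling or its pool are shared by the probes of a gene and are not in these values. Because the reference mixed the pools equally, no pool could stand far above a log2 ratio of 2, and the highest values lie near that ceiling. The 4-week and 16-week arrays correlated at r = -0.497 over probes, the 8-week and 16-week arrays at r = -0.452, and the other 4 pairs lay between -0.166 and 0.122. An equal-mix reference pushes these correlations below 0, to a mean of -0.333 if the arrays vary equally, and the mean here was -0.176.

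The first question was how the arch differed between the shortest and the longest feeding. After 16 weeks the pool held far more transcript of inflammatory and macrophage genes than after 4 weeks. Il6, an inflammatory cytokine, stood 49.1-fold higher at 16 weeks, Spp1 (osteopontin) 40.1-fold, and the monocyte chemoattractants Ccl7 and Ccl2 37.7-fold and 23.2-fold. In the opposite direction, transcripts of digestive enzymes made by the exocrine pancreas were high at 4 weeks and lower at each later time, with Try4, a trypsinogen, 306-fold lower at 16 than at 4 weeks. In all, 647 genes were at least 2-fold higher at 16 than at 4 weeks and 240 were at least 2-fold lower, together 4.52% of the genes.

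The 12 genes with the largest difference upward that moved the same way at each step were Il6, Spp1, Ccl7, Ptx3, Ccl2, Bex1, Htr2b, Rnf128, Mmp12, Ch25h, Cd72 and Mmp3. Their log2 differences ran from 5.62 for Il6 to 4.10 for Mmp3. Ptx3, a pentraxin of the acute inflammatory response, differed by 4.74. Ch25h, which makes 25-hydroxycholesterol, differed by 4.12. Mmp12 (macrophage elastase) and Mmp3 (stromelysin-1), which degrade matrix, differed by 4.13 and 4.10. Htr2b, a serotonin receptor, and Rnf128, a ubiquitin ligase, both differed by 4.30. The 12 largest differences downward were those of Try4, Prss2, Prss1, Pnliprp1, Reg2, Cpb1, Reg1, Pnliprp2, Zg16, Clps, Amy2 and Cela3b. They ran from -8.26 for Try4 to -5.81 for Cela3b. These encode trypsinogens, lipases and their cofactor, a carboxypeptidase, amylase, an elastase and other secretory proteins of the pancreas. Trypsinogen genes are close copies of each other, so a probe may read several of them and the values of Try4, Prss1 and Prss2 are uncertain as to which gene they measure. A list of 28 pancreatic acinar genes, written after these values were seen, had a median of -5.56, and all 28 were at least 2-fold lower at 16 weeks.

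**Figure D1:**
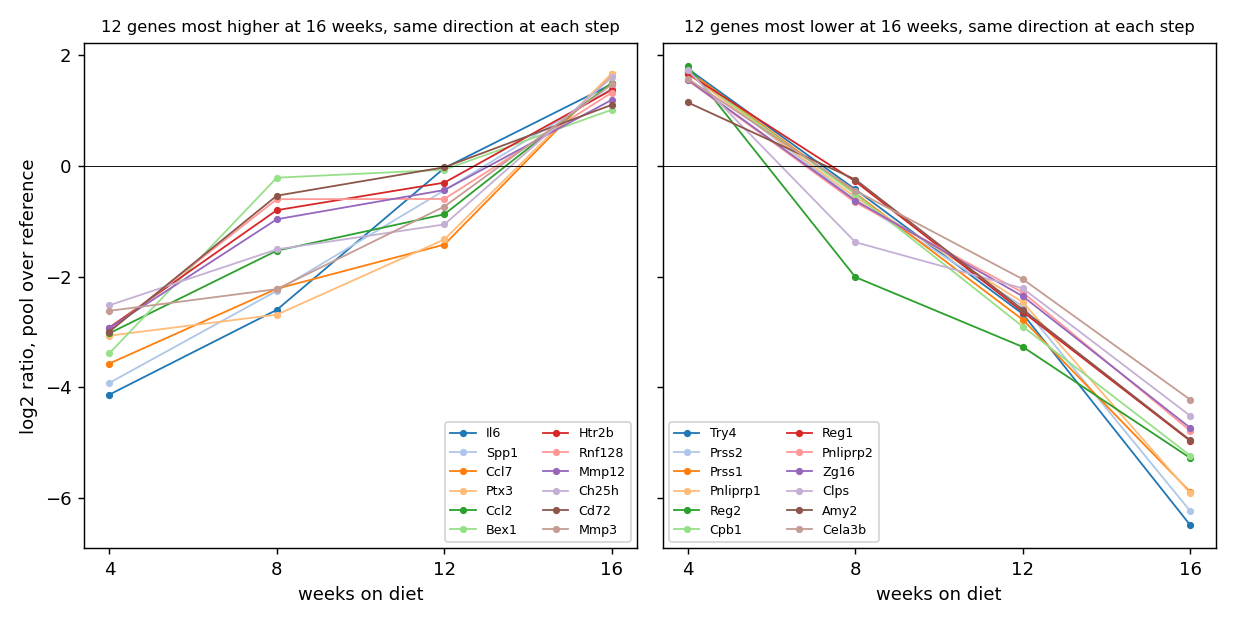
Log2 ratio of pool over reference (vertical axis) against weeks on diet (horizontal axis) for the 12 genes with the largest difference upward (left) and the 12 with the largest difference downward (right) between 16 and 4 weeks that moved the same way at each step. Each line is 1 gene and each point is 1 pool. Il6 runs from -4.14 at 4 weeks to 1.48 at 16 weeks, and Try4 from 1.76 to -6.50.

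Of the 647 genes higher at 16 weeks, 417 (64.5%) were higher at each of the 3 steps, and of the 240 lower genes 91 (37.9%) were lower at each. With quantile-normalized arrays these were 263 of 480 higher genes and 91 of 246 lower genes. A large difference between the first and last pool itself favours such an order, so these shares have no chance value here. The largest single step of the 647 lay between 4 and 8 weeks for 251 genes, between 8 and 12 weeks for 85 and between 12 and 16 weeks for 311. Set against the 8-week pool in place of the 4-week pool, the 16-week pool had 432 genes at least 2-fold higher and 391 lower. Between 12 and 4 weeks the counts were 293 higher and 143 lower.

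Macrophage genes had the highest median of the 32 lists. Of 30 measured genes of a macrophage and foam cell list, 25 were at least 2-fold higher at 16 than at 4 weeks, none was 2-fold lower, and 22 were higher at each successive time. Cd163 (-0.86) and F13a1 (-0.24), genes of resident macrophages, were lower. The list's median difference was 2.22, with quartiles of 1.71 and 2.91. Spp1 (5.33), Mmp12 (4.13), Cd5l (3.13), a scavenger-receptor family protein secreted by macrophages, and Mpeg1 (3.07), a pore-forming protein of phagocytes, differed most. The median stood at -1.50 at 4 weeks, -0.23 at 8, 0.06 at 12 and 0.75 at 16 weeks. Genes of lysosomes and cathepsins moved alike, with 19 of 24 at least 2-fold higher, 19 higher at each successive time and a median of 1.35. The cathepsins Ctss (4.01) and Ctsk (2.51), the proton pump subunit Atp6v0d2 (3.44) and the glucuronidase Gusb (2.07) led this list. Ctss has 1 probe, which lay outside the closure limit of 0.3, so its values are uncertain. With only probes inside that limit the list's median was 1.28. On the list named for targets of the sterol receptor LXR and cholesterol efflux, 7 of 17 genes were at least 2-fold higher, with a median of 0.16. They included Ch25h (4.12), the cholesterol exporter Abcg1 (2.51), the cholesterol-esterifying enzyme Soat1 (2.35) and the lipid transfer protein Pltp (1.76). The list is mixed, since Ch25h makes a sterol and Soat1 esterifies cholesterol. These 7 genes alone do not show a response of LXR or of efflux.

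Medians were set against 10000 random lists of the same size, drawn either from all genes or matched on each member's range over the 4 arrays. Against matched lists the macrophage list lay at percentile 100 and the lysosome list at 99.3, and the LXR list at 75.8. Against lists drawn from all genes, the comparison planned before, these 3 lists lay at 100, 100 and 99.35. The LXR list thus stood apart only in the planned comparison. The test of a linear trend over all genes passed 2 macrophage genes and 2 lysosome genes, and no LXR gene. The lysosome genes were Ctsk and the uncertain Ctss. Adjusted over the list alone it passed 26, 22 and 6. Members of a list share the same 4 pools, so here and below such counts are not independent tests. By the same rule all 28 genes of the pancreatic acinar list, written after the values were seen, passed. With limma's camera at a preset correlation the adjusted p was 1.00e-24, 6.37e-25 and 0.000484 for these 3 lists, and adjusted p = 0.577 with an estimated correlation for each. In the same comparison the contractile smooth muscle list had a median of -0.75, the white adipocyte list -0.67 and the immediate early and heat shock list 0.73.

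Chemokines and adhesion molecules were also higher after long feeding. Of 21 measured, 14 were at least 2-fold higher at 16 than at 4 weeks and none lower, with a median of 2.14 that lay at percentile 100 of the matched lists. Il6 (5.62), Ccl7 (5.24), Ccl2 (4.54) and Ccl3 (3.75) differed most. Complement genes had a median of 0.91 with 6 of 14 at least 2-fold higher and 1 lower, led by the anaphylatoxin receptor C3ar1 (2.91) and by C1qc (2.24), C1qb (2.14) and C1qa (2.00), the subunits of C1q that macrophages make. The complement list lay at percentile 98.99 of the matched lists. C1qa, C1qb and C1qc are on the macrophage list too, so the complement result is not separate from that one. Interferon-stimulated genes had a smaller median of 0.40 at percentile 99.85, with Ifit1 (2.83-fold) and Cxcl10 (2.51-fold) as the only 2 of 19 that were at least 2-fold higher. Adjusted over the list alone the trend test passed 16 chemokine genes, 9 complement genes and 0 interferon-stimulated genes. Over all genes it passed Il6 and Cxcl1 and no gene of the complement or interferon lists. The camera adjusted p with an estimated correlation was 0.371 for chemokines, and adjusted p = 0.577 with an estimated correlation for both other lists, where a preset correlation gave 5.05e-16, 1.09e-08 and 0.000244.

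Matrix genes and the enzymes that cut matrix were higher at 16 weeks in part. Of 25 fibrillar matrix and elastic fibre genes, 8 were at least 2-fold higher and the median was 0.56, at percentile 99.5 of the matched lists. The proteoglycan Lum (2.56), fibronectin Fn1 (2.02), thrombospondin Thbs1 (2.01) and the collagen Col5a2 (1.36) led them. Among 16 metalloproteinases and inhibitors, 7 were at least 2-fold higher with a median of 0.81, at percentile 85.7 of the matched lists. Against lists drawn from all genes it lay at percentile 100, so the list stood apart only there. Mmp12 (4.13), which is on the macrophage list too, Mmp3 (4.10), Mmp13 (3.68) and Timp1 (3.30), an inhibitor of these enzymes, differed most. Genes of TGF-beta signalling and the response to injury had a median of 0.48 at percentile 97.7, with Ccn1 (2.98), Tnfrsf11b (2.76) and Ltbp2 (1.80) as the 3 of 15 at least 2-fold higher. The trend test over all genes passed 2 metalloproteinase list genes and none of the other lists here. Adjusted over the list alone, it passed 10 matrix, 8 metalloproteinase and 2 TGF-beta genes. For these 3 lists camera gave adjusted p = 0.577 with an estimated correlation, against 6.13e-08, 4.30e-07 and 4.00e-06 with a preset correlation.

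Cartilage and bone genes stood out in the 16-week pool and not before. Their median was -0.59 at 4 weeks, -0.74 at 8, -0.14 at 12 and 0.81 at 16 weeks, and 12 of 21 were at least 2-fold higher at 16 than at 4 weeks. The bone sialoprotein gene Ibsp differed by 4.98, Chad (chondroadherin) by 4.36, Cnmd (chondromodulin) by 3.67 and the link protein gene Hapln1 by 3.06. Most of this lay in the last step. Between 12 and 16 weeks Ibsp differed by 4.61 and Chad by 4.03, and only 2 of the 21 genes were higher at each step. The list's median 16 minus 4 week difference of 1.45 lay at percentile 99.99 of the matched lists. The trend test passed no gene of the list over all genes and 4 when adjusted over the list alone. Its adjusted p from camera was 9.99e-07 with a preset correlation, and adjusted p = 0.577 with an estimated correlation. Immediate early and heat shock genes were high in the same pool, with a median of 0.65 there against -0.13, -0.97 and -0.28 at 4, 8 and 12 weeks. Egr2 (3.73), the chaperone Dnajb1 (2.40), Junb (1.99) and Egr1 (1.96) led that list. Its 16 minus 4 week median of 0.73 lay at percentile 69.2 of the matched lists. Against lists drawn from all genes it lay at percentile 100, so the list stood apart only there. Camera gave an adjusted p of 0.000171 for it with a preset correlation, and adjusted p = 0.577 with an estimated correlation.

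Contractile smooth muscle genes, the markers of the resting medial cell, were lower at 16 than at 4 weeks by a modest amount that most members shared. Of 22 genes 21 were lower and 6 at least 2-fold lower, with a median of -0.75 and quartiles of -0.97 and -0.53. The median lay below all 10000 matched lists, at percentile 0. Ramp1 (-1.39), a receptor subunit for calcitonin-family peptides, Npnt (-1.33), the smooth muscle myosin heavy chain Myh11 (-1.24) and Des (-1.15), which encodes desmin, differed most. The endothelial list had a median of -0.15, with none of 19 genes 2-fold apart and Icam2 (-0.74) farthest. It lay at percentile 9.74 of the matched lists and at 2.28 of lists drawn from all genes, so it stood apart only against the latter. Camera gave it an adjusted p of 0.368 with a preset correlation. Neither list held a gene that passed the trend test, over all genes or adjusted over the list alone. For smooth muscle camera gave 9.72e-09 with a preset correlation and adjusted p = 0.577 with an estimated correlation.

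Genes of fat, of mitochondria and of striated muscle were lower in the 16-week than in the 4-week pool. The white adipocyte list had a median of -0.67 with 6 of 19 genes at least 2-fold lower, among them Pck1 (-2.17), an enzyme of glyceroneogenesis in fat, Cfd (adipsin, -1.25), Dgat2 (-1.22), which makes triglyceride, and Adipoq (adiponectin, -1.12). The brown adipocyte list had a median of -0.54, with Ppara (-1.30) as its only gene of 16 at least 2-fold lower. The mitochondrial respiration list had a median of -0.58 with none of 24 genes 2-fold apart, and Ndufb8 (-0.84) farthest. Cardiac muscle genes had a median of -0.46, led by Tnnt2 (-0.99), and skeletal muscle genes one of -0.50, led by the fast myosin gene Myh4 (-2.71). These 5 lists lay at percentiles 0.01, 0.65, 0.04, 0.02 and 0.42 of the matched lists. None held a gene that passed the trend test, over all genes or adjusted over the list alone. For each of them camera gave adjusted p = 0.577 with an estimated correlation, where the preset correlation had given 0.000956, 0.00013, 4.65e-07, 0.000205 and 0.000292. The difference lay between 12 and 16 weeks for fat, since the medians between 12 and 4 weeks were 0.22 for white and 0.00432 for brown adipocyte genes. Skeletal muscle genes were already low at 12 weeks, with medians of -0.10, 0.89, -0.50 and -0.77 at 4, 8, 12 and 16 weeks. Their median difference between 16 and 12 weeks was only -0.13.

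**Figure D2:**
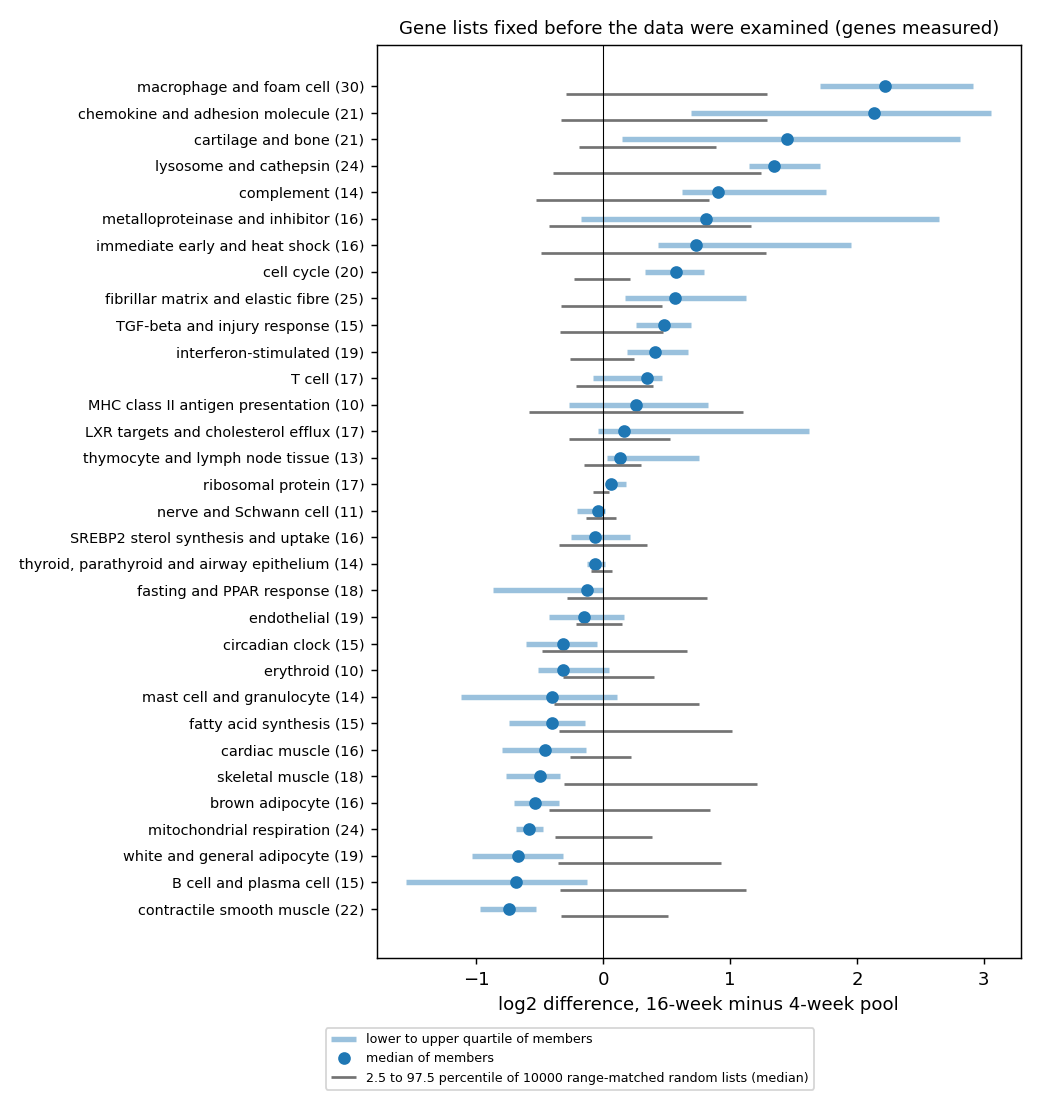
Log2 difference between the 16-week and the 4-week pool (horizontal axis) for each of the 32 gene lists fixed before the data were examined, with the number of measured genes in brackets. Points are medians of the members, thick bars run from the lower to the upper quartile of the members, and thin grey bars span the medians of 10000 random lists matched on range, less the extreme 2.5% at each end. The macrophage list has the highest median at 2.22 and the contractile smooth muscle list the lowest at -0.75.

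Lymphocyte genes followed another course, with their peak at 8 weeks. B cell and plasma cell genes had a median of 0.49 at 8 weeks and -0.59 at 16 weeks, and of 15 genes 6 were at least 2-fold lower and 2 higher at 16 than at 4 weeks. Ms4a1 (-2.01), which encodes CD20, Cd79b (-1.86), a B cell receptor subunit, and the complement receptor gene Cr2 (-1.84) were lower, while Blnk (2.18), an adaptor also made in macrophages, was higher. This list's median of -0.68 lay at percentile 0.04. Its camera adjusted p was 0.0204 with a preset correlation, and adjusted p = 0.61 with an estimated correlation. T cell genes had a median of 0.40 at 8 weeks, and for the 16 minus 4 week difference a median of 0.34 and a mean of 0.38. That median lay at percentile 96.6 of the matched lists and 100 of lists drawn from all genes. Its direction turned with the pools compared. It was -0.16 for the mean of 12 and 16 minus the mean of 4 and 8 weeks, and -0.21 for 16 minus 8 weeks. Only Il7r (3.39) and Cd8a (1.12) of 17 were at least 2-fold higher. The 16 minus 4 week median and mean of the T cell list were positive while camera's direction on the trend was down, with an adjusted p of 0.905 at a preset correlation. MHC class II genes had a median difference of 0.26, at percentile 53.3 of the matched lists and 99.57 of lists drawn from all genes. Between 16 and 8 weeks their median was -0.34. Here the alpha and beta chain genes H2-Eb1 (1.14) and H2-Aa (1.02) were higher at 16 than at 4 weeks. Both were highest at 12 weeks, at 0.32 and 0.41. The peak of H2-Ob, a modulator of peptide loading, was at 8 weeks (1.47 above the mean of the other pools). The thymocyte and lymph node list had a median of 0.13 at percentile 87.5, with Rag1 (1.79) and Dntt (1.62), genes of lymphocyte receptor assembly, as its 2 members that were at least 2-fold higher. In the same list Cxcl13, Glycam1 and Ccl21a, markers of lymph node tissue looked at after the values were seen, were highest in the 8-week pool, at 1.21, 0.98 and 0.90, as most B and T cell genes were, but the lymph node chemokine gene Ccl19 was -0.18 there and highest at 16 weeks, at 0.39. The trend test passed no gene of these 4 lists over all genes, and 1, from the thymocyte list, adjusted over the list alone.

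Granulocyte genes were highest at 12 weeks, while most mast cell genes were not. The list that joins them had a median of 0.43 in that pool and -0.37 at 16 weeks. The neutrophil granule genes Camp and Ngp and the calprotectin genes S100a8 and S100a9 stood 1.58, 1.59, 1.51 and 1.38 above the mean of the other pools at 12 weeks. The mast cell genes Cpa3 (0.27), Tpsb2 (0.30), Kit (0.40), Ms4a2 (0.29) and Cma1 (0.21), looked at after the values were seen, were highest at 8 weeks. Between 16 and 4 weeks the list's median was -0.41, at percentile 2.10, with 4 of 14 genes at least 2-fold lower and 1 higher. Camera did not call it, with an adjusted p of 0.807 at a preset correlation and 0.946 with an estimated correlation. Erythroid genes had a median of -0.32 at percentile 2.28, with the transferrin receptor gene Tfrc (1.68) as the only gene of 10 at least 2-fold apart, and camera did not call them either (adjusted p of 0.194 and 0.577).

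Genes of cell division were slightly higher after long feeding. All 20 measured genes of the cell cycle list were higher at 16 than at 4 weeks, but only Bub1 (1.59), Aurkb (1.45) and Birc5 (1.06), which act in chromosome segregation, were at least 2-fold higher. The median was 0.57 at percentile 100 of the matched lists. The trend test passed 8 of the 20 when adjusted over the list alone, and none over all genes. Camera gave 4.05e-10 with a preset correlation, and adjusted p = 0.577 with an estimated correlation.

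Genes of lipid synthesis peaked in the 8-week pool. Fatty acid synthesis genes had a median of 0.67 at 8 weeks, against 0.00 at 4, -0.27 at 12 and -0.50 at 16 weeks. Thrsp, Pnpla3, Acly and Elovl6 stood 1.62, 1.63, 1.59 and 1.43 above the mean of the other pools there. The medians of both adipocyte lists were highest in the same pool, the brown list 0.71 above the other pools at percentile 100 of the matched lists and the white list 0.47 at percentile 99.91. Elovl3 and Ucp1 stood 1.72 and 1.28 above the mean of the others there, while Adipoq (0.52), Cfd (0.89), Pck1 (0.69) and Slc27a2 (0.61) were highest at 12 weeks. Between 16 and 4 weeks the median of fatty acid synthesis genes was -0.41, at percentile 1.25. Its camera adjusted p was 0.00571 with a preset correlation, and adjusted p = 0.577 with an estimated correlation. Sterol synthesis genes had a median of 0.37 at 8 weeks, at percentile 100 against the other pools, with Idi1 and Pmvk 1.00 and 0.98 above the mean of the others. Between 16 and 4 weeks their median was -0.06 at percentile 47.8. The naming rule also planned Ldlr and Cetp where measured, but their values are not given here. Ldlr is a member of the fixed list of sterol synthesis and uptake. The fasting and PPAR list had a median of -0.12 at percentile 16.3, with the metallothionein gene Mt2 (1.42) highest and Pdk4 (-1.20) lowest, the circadian clock list -0.32 at percentile 12.4 with Bhlhe40 (2.00) highest and 2 genes with a trend adjusted over the list alone, and ribosomal protein genes 0.06 at percentile 98.96. Against lists drawn from all genes the circadian clock list lay at percentile 0.02 and the ribosomal list at 90.6. Camera called neither. Its adjusted p was 0.368 for the clock list and 0.144 for the ribosomal list at a preset correlation, and 0.577 and 0.61 with an estimated correlation. The nerve and Schwann cell list (-0.04, percentile 33.3) and the thyroid, parathyroid and airway list (-0.07, percentile 9.82) held no gene 2-fold apart.

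Of the 32 lists, 14 stood above and 12 below all but 2.5% of the random lists drawn from all genes. Chance gives 1.6 in all only if the members of a list vary independently. Members share the same pools and can move together, with an estimated correlation as high as 0.95 for the MHC class II list. The number expected by chance for such lists is therefore unknown, and 1.6 is no measure of it. Against lists matched on range the counts above and below were 10 and 10. Camera's preset correlation called 12 lists higher and 8 lower, and an estimated correlation called 0 in either direction. The latter rests on 2 residual degrees of freedom, so its 0 calls cannot decide the question. For the chemokine list the estimated correlation was -0.0385, below the preset 0.01. Its unadjusted p from camera still went from 4.73e-17 to 0.0116.

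**Figure D3:**
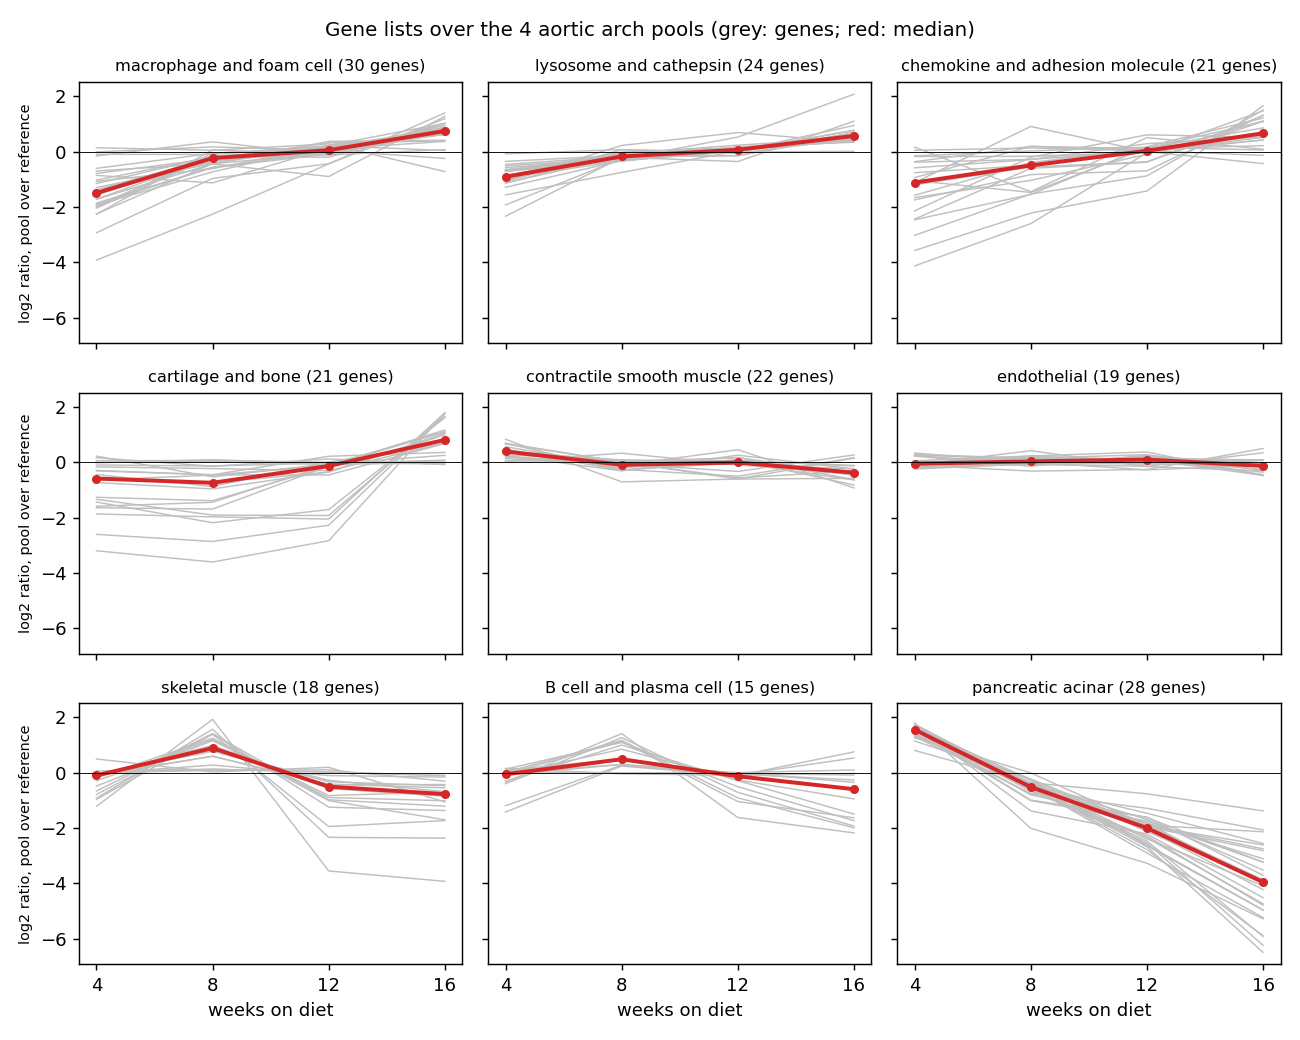
Log2 ratio of pool over reference (vertical axis) against weeks on diet (horizontal axis) for 9 gene lists. Each grey line is 1 gene and the red line joins the medians of the list at each pool. The macrophage median runs from -1.50 to 0.75, the cartilage and bone median is above 0 only at 16 weeks, the skeletal muscle median peaks at 0.89 at 8 weeks, and the pancreatic acinar median, of a list written after the values were seen, runs from 1.56 to -3.96.

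The next question was which genes changed steadily with time on diet. In a linear fit of each gene's log2 ratio on week, 23 genes rose and 18 fell at a limma adjusted p under 0.05. Spp1 rose by 1.78 ± 0.04 log2 (SE) per 4 weeks (adjusted p = 0.0063) and Il6 by 1.94 ± 0.11 (adjusted p = 0.0319). Timp1 (adjusted p = 0.0145), the chemokine gene Cxcl1 (adjusted p = 0.0435), the cathepsin genes Ctss (adjusted p = 0.0448) and Ctsk (adjusted p = 0.0248) and Il1rn, the interleukin-1 receptor antagonist (adjusted p = 0.0319), rose too, though the 1 probe of Ctss lay outside the closure limit of 0.3. So did the matrix collagen gene Col8a1, the Fc receptor gene Fcgr3, the lectin gene Clec4n, the innate sensor gene Tlr13, Ms4a6d, Adam8, Anpep, Gpr176, Rarres1, Serpina3k, Serpina3n, Milr1, Kcnk13, Htra4, Nek6 and Metrnl. Of the 18 genes that fell, Cpb1 fell by 2.32 log2 per 4 weeks (SE 0.04, adjusted p = 0.00596) and Reg1 by 2.23 (SE 0.06, adjusted p = 0.0063). Try4, Prss1, Prss2, Pnliprp1, Pnliprp2, Pnlip, Cpa1, Ctrl, Cela3b, Amy2, Zg16, Cuzd1, Gp2 and Dmbt1, genes of pancreatic enzymes, granule proteins and secretions, fell as well. These pancreatic genes moved together, and pancreatic RNA or tissue in the pools is a candidate explanation given below. The remaining 2, Ela2 and Klk6, carry older names, and the 2 probes of Klk6 disagreed with an SD of 4.26 log2 for the 16 minus 4 week difference, so that gene's value is uncertain. The fit left 2 residual degrees of freedom, and with the 4-week, the 8-week or the 16-week pool left out it called 0 genes, while without the 12-week pool it called 2 that rose and 13 that fell. Quantile normalization of the arrays left 0 calls by limma, with 1940 genes at an unadjusted p under 0.05 against 2067 as deposited, and a fit on log2 of weeks left 1 and 2.

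Step by step, macrophage and skeletal muscle genes stood higher at 8 than at 4 weeks, and pancreatic transcripts lower. Between 4 and 8 weeks 242 genes were at least 2-fold higher and 113 lower. Bex1 (3.18), Myh4 (3.15), Apol7c (2.57) and Tceal7 (2.56) were highest at 8 weeks relative to 4, and Reg2 (-3.81), Errfi1 (-3.25), an inhibitor of the EGF receptor, Clps (-3.11) and Ctrb1 (-2.60) lowest. The macrophage median differed by 1.19 and the skeletal muscle median by 0.97. With quantile-normalized arrays the counts were 167 higher and 162 lower.

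Skeletal muscle transcripts were lower at 12 than at 8 weeks. Myh4 (-5.49), Acta1 (-3.91), the actin of skeletal muscle, Bpifa1 (-3.58), a secretory protein of the airways, and Myot (-3.34) were lowest at 12 weeks relative to 8, and Mfsd2a (3.07), a lipid transporter, Il6 (2.56), C1qtnf3 (2.48) and Errfi1 (2.35) highest. The skeletal muscle median differed by -1.34, that of fatty acid synthesis genes by -0.85 and that of metalloproteinases and inhibitors by 0.86. In all 104 genes were at least 2-fold higher and 163 lower. With quantile-normalized arrays there were 198 higher and 175 lower, so the balance of the 2 directions turned with the scaling.

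Cartilage and bone genes were higher at 16 than at 12 weeks. Between 12 and 16 weeks Ibsp (4.61), Chad (4.03), Gabra3 (3.95), a GABA receptor subunit, and the immediate early gene Arc (3.85) were highest at 16 weeks, and Try4 (-3.82), Prss2 (-3.71), Pnliprp1 (-3.46) and Cyp2e1 (-3.12), a liver cytochrome P450, lowest. The cartilage and bone median differed by 1.14, at percentile 100 of lists matched on range, the macrophage median by 0.74 at percentile 98.1, the white adipocyte median by -0.84 at percentile 0 and the immediate early and heat shock median by 0.94 at percentile 99.7. At least 2-fold higher were 310 genes and lower 184, against 219 and 207 with quantile-normalized arrays.

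Each pool was also set against the mean of the other 3. The 4-week pool had 79 genes at least 2-fold above and 307 below that mean. Its highest genes were the pancreatic Reg2 (5.33), Try4 (4.96), Prss2 (4.83), Prss1 (4.78), Pnliprp1 (4.66) and Cpb1 (4.58), and its lowest Il6 (-3.75), Bex1 (-3.64), Spp1 (-3.49), Cd72 (-3.18), Rnf128 (-3.02) and Htr2b (-3.02). The 8-week pool had 118 genes above and 94 below. Skeletal muscle led it, with Myh4 (4.83), Acta1 (3.45), Myot (2.94) and Neb (2.66), together with Apol7c (2.91) and Cr2 (2.79), and the skeletal muscle list stood 1.30 above the other pools at percentile 100 of the matched lists. Errfi1 (-3.28), Ibsp (-2.19), Mt2 (-2.16), Mfsd2a (-2.11), Arc (-2.09) and Fosb (-2.09) were its lowest genes. The 12-week pool differed least, with 35 genes above and 86 below. Mfsd2a (1.99), Cyp2e1 (1.90), C1qtnf3 (1.75), Il6 (1.71), Ngp (1.59) and Cthrc1 (1.58) were highest and Bpifa1 (-2.55), Myh4 (-2.48), Gabra3 (-2.33), Rag1 (-1.90), Ppig (-1.88) and Dntt (-1.78) lowest. The 16-week pool differed most, with 419 genes above and 186 below. Ibsp (4.99), Chad (4.34), Arc (4.23), Ccl7 (4.07), Ptx3 (4.04) and Cnmd (3.76) led it, and Try4 (-6.05), Prss2 (-5.76), Pnliprp1 (-5.47), Prss1 (-5.38), Cpb1 (-4.67) and Reg1 (-4.56) were its lowest.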

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

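Probes that carry no gene name here took no part in the comparisons, and they too differed between pools. Of 16159 such probes with all 4 values, 148 were at least 2-fold higher and 99 at least 2-fold lower at 16 than at 4 weeks. No time point has a second pool, so no sample could be set against others of its group.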

How the results depend on the processing

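The alternatives 16 minus 8 weeks, 12 minus 4 weeks, random lists matched on range and leaving out genes of other tissues were chosen after the data were seen, although 12 minus 4 weeks had been planned for the lists. Setting array medians to 0, taking the median of probes, keeping genes whose probes differ by less than 1 log2 and keeping probes with closure within 0.3 each left all 14 counts within 1.5 times. The causes of the differences given here were not tested, except that thresholds and fewer arrays act by construction. The table gives no signal over background, so faint probes could not be separated from quiet genes. No paired analysis was possible because each time point has 1 pool and the counts between pools come from no test.

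At 1.5-fold the counts higher and lower were 1351 and 916 for 16 against 4 weeks, 711 and 378 for 8 against 4, 464 and 598 for 12 against 8, and 1060 and 826 for 16 against 12, and 749 and 227 genes moved the same way at each step. At 3-fold they were 296 and 66, 63 and 42, 25 and 47, 67 and 55, and 214 and 41. For 16 against 4 weeks the mean of 12 and 16 minus the mean of 4 and 8 weeks gave 290 and 85, 12 minus 4 weeks 293 and 143, and 16 minus 8 weeks 391 lower genes. Without the genes of pancreatic, liver, muscle and fat lists the counts were 647 and 192. Quantile normalization gave 198 genes higher at 12 than at 8 weeks, 263 higher at each step, and 0 rising and 0 falling trends by limma, with 1940 genes at an unadjusted p under 0.05.

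Trends numbered 1 rising and 2 falling on log2 of weeks, 14 rising under robust eBayes, and 120 and 37 at an adjusted p of 0.1. Leaving out a pool gave 0 to 2 rising and 0 to 13 falling genes, with 0 and 0 without the 4-week, the 8-week or the 16-week pool. Those fits kept 1 residual degree of freedom. Lists apart numbered 0 higher and 0 lower with camera's estimated correlation, and 7 lower for 12 minus 4 weeks.

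Some list medians changed sign with the pools compared. Between 12 and 4 weeks the medians were -0.00033 for T cells, 0.37 for mast cells and granulocytes, 0.0807 for endothelium, 0.22 for white adipocytes, 0.00432 for brown adipocytes, 0.0505 for cardiac muscle, 0.12 for erythroid genes, -0.11 for immediate early and heat shock genes, -0.00133 for thymocyte and lymph node tissue, 0.00997 for nerve and Schwann cells and 0.19 for the fasting and PPAR response. Between 16 and 8 weeks they were -0.34 for MHC class II, -0.21 for T cells and 0.27 for the circadian clock. For the mean of 12 and 16 minus the mean of 4 and 8 weeks they were -0.16 for T cells, 0.0083 for mast cells and granulocytes and -0.0128 for thymocyte and lymph node tissue, and single genes that changed sign were Cd8a (-0.0915), S100a9 (0.34), S100a8 (0.49), Pnpla3 (-0.31), Cd3g (-0.17) and Glycam1 (-0.46). A median within a few hundredths of 0 has no clear direction. Quantile normalization moved 102 of 335 differences of named genes by at least the spread between probes of a gene (0.303 log2). No list or named gene changed sign under another scaling, gene value or probe filter.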

Other observations

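The tests below were chosen after the results were seen, except that of the order of the arrays, and the 5 further acinar genes were chosen after the acinar pattern was seen but before their own values were. Besides pancreatic enzymes, genes typical of liver were higher at 4 weeks than at 16. On a list of 21 hepatocyte genes, written after the values were seen, all 21 were lower at 16 weeks with a median of -0.82, and Apoa2 (-2.93), Fabp1 (-2.74), Cyp2e1 (-2.34) and Fgb (-1.96) differed most, while Alb, the most abundant liver transcript, differed by -0.99. The list's medians were 0.30, 0.00299, 0.0658 and -0.47 at 4, 8, 12 and 16 weeks. Only 7 of the 21 genes were lower at each step, unlike the acinar genes, and Cyp2e1 was highest at 12 weeks, at 0.94. Pancreatic islet genes differed far less than acinar genes, with a median of -0.19 over 8 genes, and Iapp (-0.79), Gcg (-0.53) and Ins2 (-0.38) farthest.

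Rag1 and Dntt, both needed to assemble lymphocyte receptors, stood at 1.44 and 1.32 at 16 weeks and at -2.03 and -1.91 at 12 weeks, while Rag2 lay between -0.02 and 0.12 over the 4 pools. Xist, the transcript that silences an X chromosome in females, was 1.12 at 4 weeks and -0.86, -0.89 and -1.07 at 8, 12 and 16 weeks. The Y-linked genes Eif2s3y and Uty were not low at 4 weeks, with 0.18 and 0.23, and were lowest at 12 weeks, with -0.35 and -0.43. The Y-linked list of 4 genes had a median 16 minus 4 week difference of -0.13. The sex of the mice is not given in the sources used here.

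Pancreatic acinar transcripts were lower from pool to pool, with list medians of 1.56, -0.51, -2.00 and -3.96. The pattern stayed under the 3 scalings tried, where the median 16 minus 4 week difference of the list was at its highest -4.12. The deposited arrays already lay near 0, so setting their medians to 0 could not have removed it. Normalization that depends on intensity was not tested. Pancreatic RNA or tissue in the pools, in a share that shrank with time, is a candidate explanation. Of 5 measured acinar genes not used to find the pattern, 4 ran in the falling order of the pools. Among these Aqp12 differed by only -0.18 between 16 and 4 weeks, less than the pooled SD of 0.30 between probes. The others were Pla2g1b (-2.03), Tmed6 (-1.74) and Cckar (-1.38). The median of the 5 was -1.38, far from the -5.56 of the list that showed the pattern. Falling expression of these genes by cells of the arch cannot be told apart from this, because there is 1 pool per time point.

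Cartilage and bone transcripts stood out at 16 weeks. Airway tissue with its cartilage stays open, since Bpifa1, the only 1 of 4 airway transcripts that varied by more than 1 log2, differed by -1.756 between 16 and 8 weeks but by 1.83 between 16 and 12 weeks, and a single transcript cannot exclude it. Rib or sternal cartilage stays open too, since Matn1, a gene of hyaline cartilage outside the joints, differed by -0.00543 from the mean of the other pools and hardly varied in any pool, so its probe may not report. Chondrocyte-like change of lesion cells late in feeding, which time on diet would allow, was not tested and stays open, and immediate early genes stood out in the same pool.

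Macrophage transcripts were higher at 16 than at 4 weeks. A lower share of smooth muscle RNA alone would raise all other cell types alike, but the lower quartile of the macrophage list lay 1.548 log2 above the upper quartile of the endothelial list. A lower share of fat alone would raise smooth muscle genes too, and the upper quartile of that list was -0.527. The 3 scalings tried left a median of at least 1.702, and normalization that depends on intensity was not tested. More macrophages in the arch, or more of these transcripts per macrophage, are hypotheses that remain open and may both hold, and 1 pool per time point leaves differences between pools of the same age untested.

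The 4 arrays can be put in 12 orders over the weeks if an order and its mirror count once. Only 1 of the 12, the real order, gave as many as 41 genes with a trend, and the highest of the others gave 0, with up to 2316 genes at an unadjusted p under 0.05 by limma against 2067 in the real order. With 12 orders no share under 0.05 can be reached. Of the 41 genes 18 fell, most of them pancreatic genes that moved together, so the calls are not independent.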
